A study of Homo sapiens with 4 samples.

How the data were processed

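SW480 colon adenocarcinoma cells were grown in medium with 10% fetal bovine serum, treated for 10 h with 15% (v/v) B. mojavensis postbiotic (BM) or 15% MRS medium, and 5 μg of total RNA per sample was reverse-transcribed and labelled, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The 4 samples lay on 2 arrays, 1 MRS and 1 BM sample of the same replicate number on each, without a dye swap.

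Per the file headers, the authors deposited for each array and each of 3840 spots the mean raw intensity and the mean local background of both channels, and a net intensity. In the MRS channel the deposited net intensity equals raw minus background, floored at 0. In the BM channel the deposited net intensity holds a further factor that falls with intensity, with a median of 1.30 in the dimmest and 0.974 in the brightest 10% of spots on array 1 and of 1.19 and 0.971 on array 2. The series matrix values equal the net intensities after rounding, so their scale is linear intensity in arbitrary units, they are not centred, and each column is 1 sample (medians 1881 and 2082 for MRS, 1886 and 2100 for BM). The image software and the method behind that factor are not given in the sources used here, and the submitters' processing notes name R 4.2.2 without its role. The authors' deposited table gives a z ratio per spot, a score that per the file headers and the values is the difference of the groups' z-scores of globally scaled log2 mean intensities, divided by the SD of that difference, and a fold change on a logarithmic scale. The deposited p-value equals that of a one-sided paired test on the linear net intensities of the 2 pairs, and the table's second p column was not used.

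Raw intensities were background-corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3), with the 54 control oligonucleotide spots at weight 0 and then left out. The spots of a probe were averaged, and the probe with the highest mean log2 intensity stood for its gene. Of 1856 probes, 1701 were named by accession through an NCBI RefSeq table of the human assembly GRCh38, 75 by symbol or synonym, 5 kept the name in the file and 75 stayed unnamed. For 10 probes the accession named another gene than the file did, and the accession was followed. In 12 genes with several probes, the sign of the mean ratio differed between probes in 8. Fold changes and ratios here come from within-array differences and show unequal change, not absolute amounts.

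Genes were tested with limma (an intercept on the 2 ratios, eBayes, Benjamini-Hochberg over 1843 genes, threshold 0.05, two-sided), with 1 residual degree of freedom per gene before moderation, a prior of 3.46 degrees of freedom and a prior SD of 0.083. P-values set the mean ratio against the spread between 2 pairs of cultures, drawn by the prior towards a spread pooled over genes. Each ratio keeps the array, and with it the replicate number, as a block, so the analysis is paired. The pairing comes from the labels. The 2 channels of an array correlated over spots at 0.998 and 0.996 in log2 of raw minus background intensity. Between arrays, the log2 intensity of genes, averaged over both channels, correlated at 0.928. The channels of an array share their printed spots, so these values do not test the pairing of the cultures. Camera with a preset inter-gene correlation of 0.01 tested 27 of 39 gene lists, those with at least 5 measured genes, and camera with an estimated correlation and fry were run beside it. The lists not tested were those of heat shock (3 genes measured), NRF2 (4), metallothioneins (2), pattern recognition (3), oxidative phosphorylation (1), cholesterol (2), fatty acid synthesis (3), autophagy and lysosome (4), ribosome biogenesis (4), the proteasome (1), tRNA synthetases (2) and hepatocyte and neuron markers (4).

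The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took up to 12 genes per direction past the threshold, filled with named genes above background that had the same sign on both arrays, in order of the smaller of their 2 absolute log2 ratios, then up to 4 members per list described in the same order, and ACTB, GAPDH and colon markers. A probe counted as above background at 1.5 times its local background, and 1806 genes did so in at least 1 channel on both arrays. At most 2 spots per channel were at the scanner's maximum, and they were kept.

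The steps were tested on simulated data made from the real MRS intensities, the real intensity trend and noise drawn from the fitted prior, with 10 simulations of 200 changed genes among 1843. In them 6.96% of the genes called were unchanged ones. In 10 simulations without change, 10 genes in all and 0 lists were called. With the ribosomal list (22 measured genes) shifted by a log2 of 0.15 it was called in all 10 simulations, and 1 call of another list was made over them. That shift is larger than the list's observed mean log2 ratio of 0.049, and the simulated noise was independent between probes. Smaller shifts, shifts of other lists and correlated genes were not simulated. Alternatives covered the background correction, offset, normalization within and between arrays, a filter on dim probes, the choice of probe, the series matrix values, eBayes options, a fit without the replicate block, left-out arrays and samples, and other ways of calling, among them a z-score over a sliding window of 50 genes of like intensity. Figures were drawn with matplotlib 3.10.9.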

Results

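Gene expression was measured on 2-colour oligonucleotide arrays in SW480, an established cell line from a colon adenocarcinoma. Cells were treated for 10 h with 15% (v/v) of a postbiotic of the bacterium Bacillus mojavensis (BM), that is, a preparation from a culture of the bacterium, or with the same volume of the bacterial growth medium, MRS, as the control. Each group held 2 samples, which the submitters describe as grown and harvested independently. Their own names for the samples number the pairs 2 and 3, and whether further pairs were made is not given in the sources used here. Array 1 held MRS replicate 1 and BM replicate 1, and array 2 held MRS replicate 2 and BM replicate 2. The control was labelled with Alexa Fluor 555 and BM with Alexa Fluor 647 on both arrays, so a dye effect on a gene cannot be told apart from the treatment in any value below. The groups come from the sample titles, because the treatment field lists MRS medium for all 4 samples. The median raw spot intensity was 1985 and 2186 in the MRS samples and 1655 and 1895 in the BM samples, against median local backgrounds of 49.6, 51.9, 79.5 and 101.7, and 97.2% of the 3786 non-control spots reached 1.5 times their background in all 4 samples. All ratios are log2 of BM over MRS, and the number of arrays limits their precision.

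The main comparison asks which genes differ between BM-treated and MRS-treated SW480 cells. The largest ratio that both arrays shared was that of SLC22A3, an organic cation transporter, at -0.39 ± 0.0051 (SD, n = 2), or 0.762-fold in BM. RALB, a Ras-like small GTPase, stood at 0.33 ± 0.0065 and CD80, a costimulatory ligand of immune cells, at 0.34 ± 0.051 (SD, n = 2), both 1.26-fold. After loess, the mean ratios of the 1843 genes ran from 0.762-fold to 1.32-fold, a range that holds for this normalization only. None passed the test: limma gave 0 genes under an adjusted p of 0.05, the smallest adjusted p was 0.560, and 121 genes had an unadjusted p under 0.05, of which 60 were higher and 61 lower in BM.

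The 12 genes highest in BM on both arrays, none of which passed after loess, were of mixed function. The rule that named them and the 12 lowest takes large ratios of one sign on both arrays, which favours small SDs. Besides RALB and CD80, and in no order of size, they held DUT, the enzyme that removes dUTP, at 0.27 ± 0.0082 (SD, n = 2 here and below). PPARG, a lipid-sensing nuclear receptor, stood at 0.27 ± 0.076, and ACVR1B, an activin receptor, at 0.26 ± 0.047. The efflux transporters ABCC4 and ABCC3 stood at 0.24 ± 0.0049 and 0.22 ± 0.0029. ABCC4 was the dimmest of the 12, with a log2 intensity of 7.72 on array 1 and 9.67 on array 2, against a median of 10.9 over all genes. The ribosomal protein gene RPL5 had 0.24 ± 0.028, the lysosomal protease gene CTSZ 0.25 ± 0.048 and the cohesin subunit gene STAG1 0.23 ± 0.0062. DCT, an enzyme of melanin synthesis, had 0.33 ± 0.15, and BCAN, a proteoglycan of the brain, 0.23 ± 0.0046. RPL5 and CTSZ moved with the normalization and stood at 0.082 and 0.13 with print-tip loess and at 0.091 and 0.13 with the series matrix values, but at 0.73 and 0.73 with median centring, under which they passed (adjusted p = 0.0125, limma), as did DUT at 0.76, RALB at 0.48 and SLC22A3 at -0.44.

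The 12 genes lowest in BM on both arrays also did not pass. SLC22A3 was followed by VGLL3, a cofactor of TEAD transcription factors, at -0.36 ± 0.22, PATZ1, a zinc finger transcription factor, at -0.34 ± 0.12, and SERPINB1, an inhibitor of serine proteases, at -0.34 ± 0.096. The zinc finger gene ZNF71 had -0.30 ± 0.097, the glucose transporter gene SLC2A8 -0.28 ± 0.085 and TFG, which acts in export from the endoplasmic reticulum, -0.29 ± 0.0032. The imprinted gene MEST stood at -0.25 ± 0.062, the adaptor gene YWHAE at -0.24 ± 0.021 and the phosphatase gene CTDSP2 at -0.23 ± 0.039. NR2C2, a nuclear receptor, had -0.23 ± 0.038, and WIPF1, an actin regulator, -0.22 ± 0.024. Several were dim against a median log2 intensity of 10.9 over all genes. On arrays 1 and 2 MEST stood at 7.09 and 7.66, SERPINB1 at 7.63 and 8.28 and NR2C2 at 7.71 and 7.98. VGLL3 stood at 7.85 and 8.46, YWHAE at 7.69 and 9.05, SLC22A3 at 10.2 and 9.70 and ZNF71 at 11.4 and 10.8, and the others lay above the median. With median centring in place of loess, PATZ1 and CTDSP2 turned to 0.010 and 0.036, and SLC2A8 and WIPF1 stood at -0.11 and -0.13. CTDSP2 stood at -0.094 with print-tip loess, and MEST at -0.49 with plain background subtraction and -0.40 with the series matrix values.

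**Figure D1:**
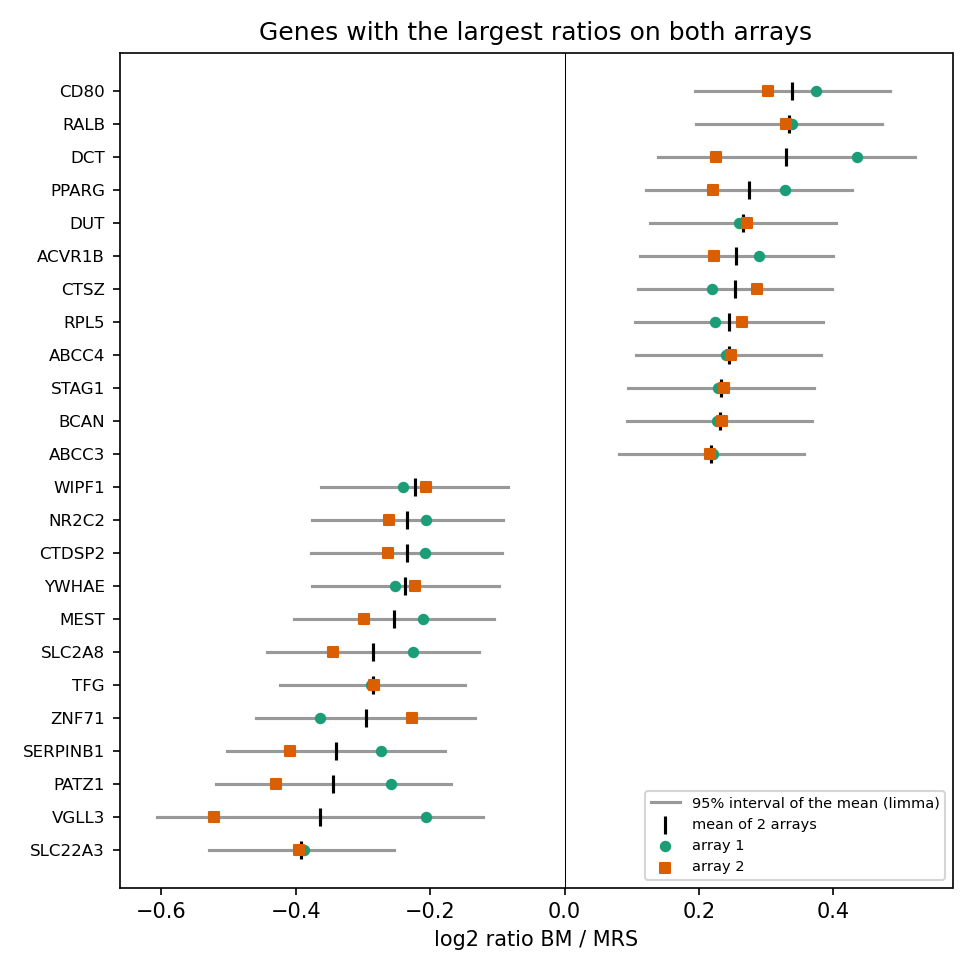
Log2 ratios of BM over MRS (horizontal axis) for the 24 genes named by their ratios on both arrays (vertical axis), with circles for array 1, squares for array 2, a tick for the mean and a grey line for limma's 95% interval, not adjusted for the number of genes. The means run from -0.39 for SLC22A3 to 0.34 for CD80, and the adjusted p was 0.560 for each of them.

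The intervals rest mostly on a spread pooled over genes (3.46 prior degrees of freedom) and less on the 2 ratios of a gene (1 degree of freedom). SLC22A3, with an SD of 0.0051, thus had a standard error of 0.052. They do not cover a dye effect or signal from other sources, and are not adjusted over genes. The 95% interval of the mean log2 ratio had a median half-width of 0.15 and lay within 2-fold for all 1843 genes and within 1.5-fold for 1838 of them. On simulated arrays with 200 of 1843 genes changed, the same limma test recovered 97.1% of changes of log2 1, 86.3% of changes of log2 0.5 and 19.7% of changes of log2 0.25. The adjusted threshold loosens as more genes change strongly, so these shares hold for that mix. Fewer or only small changes were not simulated and would be recovered less often. Simulated arrays with no changed gene gave 98 to 134 genes with an unadjusted p under 0.05 (median 117.5), a range that holds the 121 observed. That range lies above the 92.2 that would pass at the nominal rate. It also lies above the 75 that passed in the real data with the sign of array 2 turned. It thus does not settle whether 121 is a count by chance. Median centring, which leaves the intensity trend of each array in the ratios, called 34 genes (33 higher and 1 lower in BM), and 33 of these 34 were among the brightest 10% of genes. Without 1 sample at a time and without the array as a block, the sign turned at least once for 47 of the 76 genes named. In such a fit the difference between the 2 arrays enters the ratio and moves it by construction, so these turns do not test the paired ratios.

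The gene lists ask whether genes of a known function shifted together. Square brackets after a member give the lowest and highest log2 ratio over the settings that keep all samples, where one of them moved it by over 1.5 times. The group of drug efflux and conjugation genes, which export or inactivate foreign compounds, had 4 of 8 measured members higher in BM on both arrays and 1 lower. ABCC4 and ABCC3 passed when adjusted over the list alone (adjusted p = 0.0424 for each, limma), and 0 of the 8 passed over all genes. Of the 27 lists, 1 held such a member, and that adjusted p does not account for the number of lists tried. GSTP1, which conjugates glutathione, had 0.075 ± 0.0013 [0.024 to 0.15] and ABCG2, another efflux pump, -0.059 ± 0.054 [-0.062 to -0.024]. Of the 22 cytosolic ribosomal protein genes, 10 were higher on both arrays and 4 lower, with RPL5 as above, RPS19 at 0.24 ± 0.20, RPL13 at 0.091 ± 0.0049 [0.041 to 0.14] and RPS3 at 0.090 ± 0.0088 [0.042 to 0.092]. Their median log2 ratio was 0.045 on array 1 and 0.052 on array 2, and the median of their mean ratios was 0.029, which turned to -0.0078 with print-tip loess. Camera gave an unadjusted p of 0.0185 for drug efflux and 0.0132 for ribosomal proteins, an adjusted p of 0.25 for both, and 0 of 27 lists passed. With print-tip loess, camera's adjusted p was 0.0713 for drug efflux and 0.909 for ribosomal proteins. With median centring it was 0.408 for both. With an estimated correlation, the smallest adjusted p over the 27 lists was 0.952, with fry it was 0.766, and with the mixed test of fry 0.0793, for leukocyte markers. These other tests were not run on simulated arrays, so whether they could call a shifted list on 2 arrays is not known.

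Of the 11 measured p53 target genes, 2 were higher in BM on both arrays, 5 were lower and 4 had opposite signs. DDB2, a damage-recognition factor, stood at 0.23 ± 0.064 and the phosphatase gene PPM1D at 0.11 ± 0.046 [0.036 to 0.14], while MDM2, the ligase that degrades p53, stood at -0.21 ± 0.075 and BAX at -0.077 ± 0.013 [-0.13 to -0.014]. Pro-apoptotic genes had 2 of 12 higher and 4 lower, with the initiator caspase gene CASP8 at -0.18 ± 0.10 and the death receptor gene TNFRSF10A at 0.10 ± 0.037 [0.099 to 0.16]. Anti-apoptotic genes had 2 of 6 higher and 1 lower, with the caspase inhibitor gene CFLAR at 0.11 ± 0.017 [0.082 to 0.20] and BCL2 at 0.14 ± 0.12 [0.066 to 0.34]. Camera gave an adjusted p of 0.923, 0.844 and 0.821 for these 3 lists, and no member passed over all genes or when adjusted over the list alone.

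Proliferation genes gave small ratios. Of 13 genes of G2/M and mitosis, 3 were higher on both arrays and 0 lower, with the topoisomerase gene TOP2A at 0.10 ± 0.084 [0.037 to 0.11] and the mitotic kinase gene CDK1 at 0.046 ± 0.037 [0.029 to 0.071]. Of 9 genes of G1/S and DNA replication, 1 was higher (TYMS, 0.024 ± 0.0014, and -0.025 with median centring) and 1 lower (CCNA2, -0.043 ± 0.024, but 0.011 with print-tip loess and 0.032 with the series matrix values). Of 10 targets of WNT and beta-catenin, the pathway that drives most colon carcinomas, 1 was higher and 3 lower, with PPARD at -0.12 ± 0.012 and CD44 at -0.081 ± 0.0054. The median of the WNT targets' mean ratios was 0.025 (-0.0080 with the series matrix values), while their mean was -0.012 and camera put them down (adjusted p = 0.942). DNA damage repair genes had 4 of 27 higher and 7 lower, with the damage-signalling kinase gene ATM at -0.084 ± 0.0048 [-0.14 to -0.051]. The adjusted p from camera was 0.844 for G2/M and 0.942 for G1/S and for DNA repair, and in each of these 4 lists 0 genes passed when adjusted over the list alone.

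Signalling and inflammatory genes gave no shift that passed. NF-kB and inflammatory cytokine genes had 3 of 17 higher on both arrays and 7 lower, with IL1B at -0.11 ± 0.022 and the NF-kB inhibitor gene NFKBIA at -0.094 ± 0.023, both of which turned to positive values (0.13 and 0.22) with median centring. Interferon response genes had 3 of 9 higher and 3 lower, among them the peptide transporter gene TAP1 at 0.13 ± 0.056 [0.083 to 0.17] and IFIT3 at -0.10 ± 0.020, which turned to 0.15 with median centring. Immediate early and MAPK feedback genes had 4 of 14 higher and 2 lower, with FOS at 0.064 ± 0.039 [0.022 to 0.065] and IER3 at 0.14 ± 0.14 [0.052 to 0.16]. Genes of PI3K, AKT, mTOR and growth factor receptors had 8 of 17 higher and 4 lower, and the kinase genes MTOR, EGFR and BRAF stood at -0.16 ± 0.017 [-0.16 to -0.090], -0.14 ± 0.068 [-0.19 to -0.071] and -0.12 ± 0.0030, while TSC2, a brake on mTOR, stood at 0.084 ± 0.049 [0.054 to 0.086]. TGF-beta and BMP genes had 2 of 12 higher and 3 lower, with SMAD3 at 0.15 ± 0.051 [0.097 to 0.18] and the receptor gene TGFBR2 at -0.10 ± 0.076. Histone deacetylases and chromatin regulators had 0 of 14 higher and 3 lower, with HDAC2 at -0.17 ± 0.011 (0.091 with median centring). The smallest adjusted p from camera in these 6 lists was 0.821, for the immediate early genes, and 0 members passed when adjusted over the list alone.

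Markers of the colon epithelium had 3 of 11 measured members higher in BM on both arrays and 2 lower. The adhesion molecules CEACAM5, the carcinoembryonic antigen, and CEACAM1 stood at 0.10 ± 0.064 and 0.11 ± 0.076 [0.039 to 0.23 for CEACAM1], the mucin gene MUC2 at 0.12 ± 0.13 [0.070 to 0.15] and the surface antigen gene GPA33 at -0.14 ± 0.16. The list's median was positive on each array (0.053 and 0.028), but the median of the mean ratios was -0.019 (0.013 with median centring), their mean was 0.0026 and camera put the list up (adjusted p = 0.923). The reference genes ACTB and GAPDH had 0.034 ± 0.062 and 0.020 ± 0.0083, and turned to -0.0039 and -0.017 with median centring. Both lay below the median log2 intensity of 10.9 over all genes. On arrays 1 and 2 ACTB stood at 8.83 and 9.93 and GAPDH at 8.82 and 9.44. Of cell types the culture should lack, leukocyte markers had 2 of 8 higher and 2 lower, with PTPRC at -0.20 ± 0.0073 and LYZ at 0.079 ± 0.019, and fibroblast markers 1 of 8 higher and 3 lower, with COL1A2 at -0.17 ± 0.088 and COL1A1 at 0.084 ± 0.0075 [0.035 to 0.11]. Camera gave these 2 lists an adjusted p of 0.942 and 0.821. The median and mean ratio of the leukocyte markers were -0.0020 and -0.0046, while camera's direction was up, and their median turned positive with plain background subtraction, median centring, dim probes left out and the series matrix values.

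**Figure D2:**
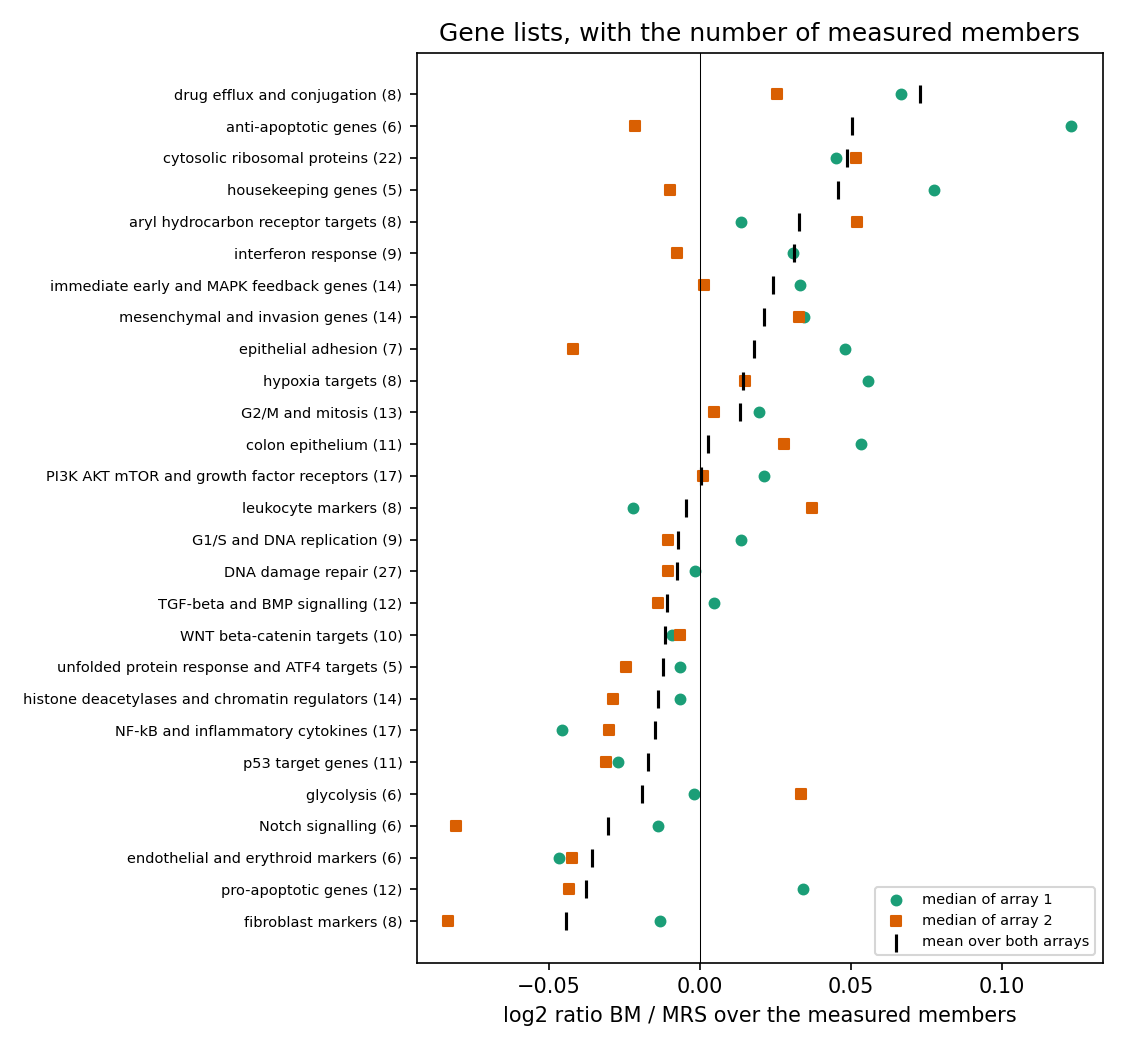
Log2 ratio of BM over MRS (horizontal axis) for the 27 gene lists with at least 5 measured genes (vertical axis, number measured in brackets), with the median over members on array 1 (circles) and array 2 (squares) and the mean over members and arrays (ticks). The medians have the same sign on both arrays in 18 of the 27 lists, and 0 lists passed camera's adjusted p of 0.05.

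The comparison of the 2 arrays asks how far the 2 independent pairs of cultures gave the same ratios. SLC22A3 (-0.39 and -0.40), RALB (0.34 and 0.33), DUT (0.26 and 0.27) and ABCC4 (0.24 and 0.25) had nearly equal ratios on both, but most genes did not. Across the 1843 genes, which are not independent replicates, Pearson's r was 0.108 and Spearman's rho was 0.0842. The sign was shared by 980 genes (53.2%), and 0 genes reached an absolute log2 ratio of 1 on either array. Within an array, duplicate spots of a probe had ratios that correlated at 0.919 (array 1) and 0.878 (array 2). The correlation between arrays was 0.445 with median centring, 0.0673 with print-tip loess and 0.0484 with the series matrix values.

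**Figure D3:**
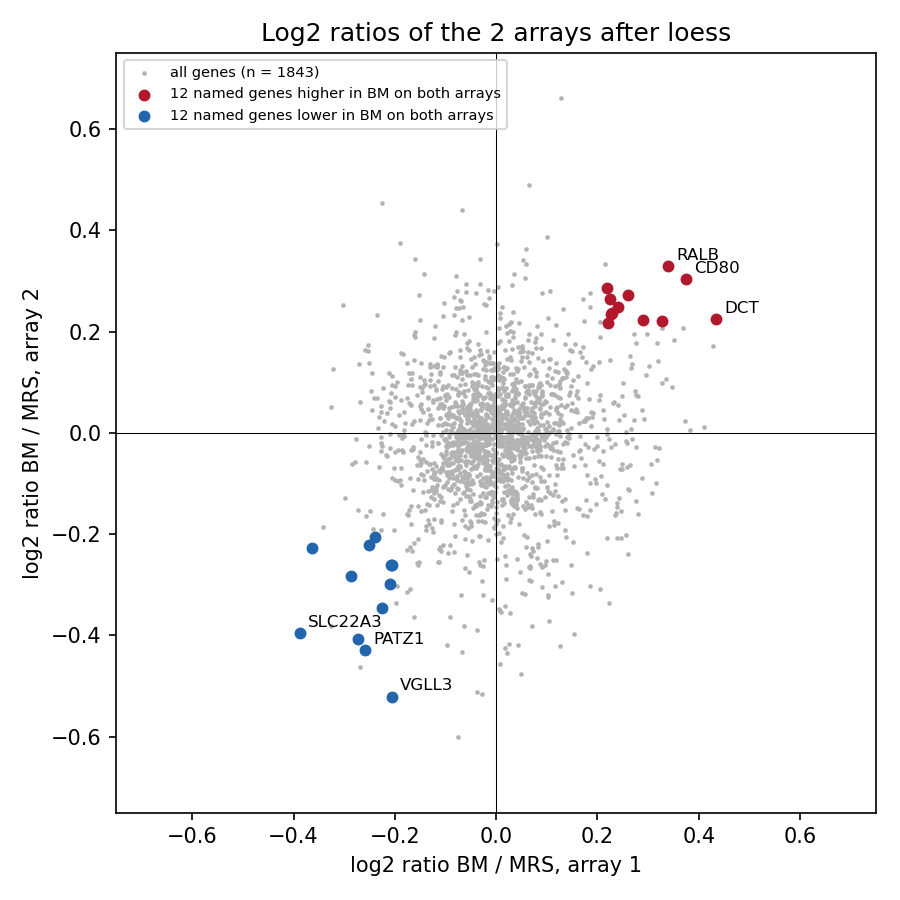
Log2 ratio of BM over MRS on array 1 (horizontal axis) against array 2 (vertical axis) for 1843 genes (grey), with the 12 named genes higher (red) and the 12 lower (blue) in BM on both arrays. The cloud has little slope (Pearson's r = 0.108), and SLC22A3, PATZ1, VGLL3, RALB, CD80 and DCT lie at its corners.

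An intensity-dependent z-score within each array, with the same sign and a size of at least 2 on both arrays, was met by 11 genes. CD80, DCT and DDB2 were higher in BM by this measure, and SLC22A3, SERPINB1, PATZ1, VGLL3, MEST and NR2C2 were lower, as were MAGEB2, a testis antigen gene named here after its values were seen, and 1 probe without a symbol. At that size 2 genes had opposite signs on the arrays (exact two-sided binomial p = 0.0225 for 11 against 2, over genes that are not independent), and 2.50 genes with a shared sign would be met if the arrays were independent. This measure gives no error rate per gene, and a dye effect would repeat on both arrays as a treatment effect would. SERPINB1, VGLL3, MEST and NR2C2 were among the dim genes given above.

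The authors' deposited table compares the groups by a z ratio per spot. In it, 183 spots had an absolute z ratio of at least 2, a threshold chosen here, with 94 higher and 89 lower in BM, and its fold changes ran from 0.704 to 1.495. A z ratio of 2 in the authors' deposited table matched a fold of 1.15, and -2 a fold of 0.860. Of those 183 spots, 147 (80.3%) had the same sign on both arrays after loess, and 96.2% of as many spots with the largest mean loess ratio did, while 89.6% of as many spots with the largest difference between the arrays had opposite signs. Both duplicate spots passed for 59 probes of the authors' deposited table. Of the 24 genes named by their ratios on both arrays, 20 had a mean z ratio of at least 2 in size and of the same sign in the authors' deposited table, from 3.22 for ABCC4 and 2.92 for CD80 to -4.23 for SERPINB1 and -4.35 for VGLL3. The other 4 fell short of it in the authors' deposited table, with 0.848 for RPL5, 1.22 for CTSZ, -1.59 for CTDSP2 and -1.995 for WIPF1. The z ratio comes from the same 4 samples and correlated at 0.866 with the mean loess ratio over spots. The 24 genes were picked for large shared ratios, so this overlap is no independent support. A large mean also favours a shared sign, and ABCC4 (on array 1), SERPINB1 and VGLL3 were dim. In the authors' deposited table the p-values were under 0.05 for 364 spots (9.61%, where a one-sided test taken in the observed direction gives 10% by chance), and 0 spots passed after Benjamini-Hochberg adjustment (smallest adjusted p 0.0692).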

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

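Of 15 other settings with a test per gene, 14 gave 0 genes under an adjusted p of 0.05, as the main setting did, with a smallest adjusted p of 0.312 to 1.00, and every setting gave 0 lists, with a smallest adjusted p of 0.0551 (series matrix values) to 0.952. Median centring called 34 genes (smallest adjusted p 0.0125), nearly all of them bright, and there RALB, DUT, RPL5, CTSZ and SLC22A3 passed. Counting by an unadjusted p under 0.05 gave 121 genes, the z-score on both arrays 11 and an absolute log2 ratio of 1 on both arrays 0. Without the replicate block, that is unpaired over the single channels, 0 genes (smallest adjusted p 1.00) and 0 lists (0.807) passed. Calls over all genes and over lists were thus 0 with and without the block. Without the block the difference between the 2 arrays enters the error, so 0 calls there say little about the block. That fit and the 4 without 1 sample are among the 15 settings. The adjustment over a list alone, which ABCC4 and ABCC3 passed, was not run without the block. The correlation between arrays was 0.445 with median centring, 0.0673 with print-tip loess and 0.0484 with the series matrix values, and 0.105 to 0.129 otherwise. With median centring the log2 ratio turned to 0.010 for PATZ1, 0.036 for CTDSP2, -0.025 for TYMS, 0.13 for IL1B, 0.22 for NFKBIA, 0.15 for IFIT3, 0.091 for HDAC2, -0.0039 for ACTB and -0.017 for GAPDH, and list medians turned to 0.0048 for pro-apoptotic genes, -0.025 for G1/S, -0.019 for G2/M, 0.013 for colon epithelium and 0.052 for leukocyte markers. CCNA2 turned to 0.011 and the ribosomal median to -0.0078 with print-tip loess. With the series matrix values CCNA2 turned to 0.032 and the medians of p53 targets, WNT targets and leukocyte markers to 0.00079, -0.0080 and 0.0049. The G1/S median turned to -0.016 with no background correction, and that of leukocyte markers to 0.028 with plain subtraction and 0.014 with dim probes left out. Of the 76 genes named, the log2 ratio turned or moved by over 1.5 times for 34 with median centring, 22 with the series matrix values, 20 with print-tip loess, 2 with no background correction, 1 with plain subtraction (MEST) and 1 with the mean of its probes (BCL2). The cause of these turns and moves was not tested. One array alone gives ratios with no test, so the list and gene counts and the correlation have no value without replicate 1 or 2. Without 1 sample at a time the fit has no block and its lone sample is assumed to vary like the other group, and 0 genes and 0 lists passed in all 4 such fits. There the difference between the 2 arrays enters the ratio, which by construction moves it, and 47 of the 76 genes followed turned sign at least once. Their lowest and highest log2 ratios without 1 replicate or sample were CD80 -0.34 to 1.01, ABCC4 -0.51 to 1.00, STAG1 -0.17 to 0.64, BCAN -0.31 to 0.77, PPARG -0.012 to 0.56, ABCC3 -0.0088 to 0.45, SLC22A3 -0.82 to 0.035, ZNF71 -0.66 to 0.067, SLC2A8 -0.71 to 0.14, YWHAE -0.67 to 0.20, CTDSP2 -0.72 to 0.25, GSTP1 -0.14 to 0.29, ABCG2 -0.26 to 0.14, RPS19 -0.60 to 1.09, RPL13 -0.10 to 0.29, PPM1D -0.16 to 0.39, BAX -0.49 to 0.33, CASP8 -0.40 to 0.028, CFLAR -0.15 to 0.38, PPARD -0.41 to 0.18, CD44 -0.48 to 0.32, CCNA2 -0.59 to 0.50, TYMS -0.33 to 0.37, TOP2A -0.10 to 0.30, NFKBIA -0.20 to 0.010, IFIT3 -0.25 to 0.041, BRAF -0.35 to 0.11, SMAD3 -0.075 to 0.37, MMP2 -0.0061 to 0.26, CXCR4 -0.55 to 0.29, CEACAM5 -0.071 to 0.28, CEACAM1 -0.14 to 0.35, FOS -0.45 to 0.57, IER3 -0.25 to 0.52, PTPRC -0.62 to 0.22, LYZ -0.034 to 0.19, COL1A2 -0.83 to 0.49, ACTB -0.33 to 0.40, GAPDH -0.044 to 0.085, DNAJC3 -0.19 to 0.41, JAG2 -0.33 to 0.18, TIE1 -0.15 to 0.030, CTNND1 -0.22 to 0.40, CA12 -0.17 to 0.35, MUC2 -0.053 to 0.29, GPA33 -0.39 to 0.12 and TSC2 -0.12 to 0.29. Leaving out dim probes changed no call, and 1806 genes were above background, a level that control spots reached too.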

Other observations

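The test of leukocyte marker probes and the value over all 5 repeated probes were chosen after the results they bear on had been seen, and the other tests before their results were. Other gene groups had members that shared a sign on both arrays, as 53.2% of all genes did. Aryl hydrocarbon receptor genes, which respond to planar ring compounds, had 4 of 8 members higher in BM on both arrays and 0 lower, led by the quinone reductase gene NQO1 at 0.23 ± 0.055 (SD, n = 2), and it did not pass when adjusted over the list alone (adjusted p = 0.0831, limma). Endothelial and erythroid markers had 0 of 6 higher and 5 lower, with TIE1 at -0.060 ± 0.0034 [-0.10 to -0.058 over the settings that keep all samples], and Notch genes had 1 of 6 higher and 3 lower, with the ligand gene JAG2 at -0.076 ± 0.041. Glycolysis genes had 2 of 6 higher and 0 lower, with the hexokinase gene HK2 at 0.064 ± 0.0084 (0.33 with median centring, 0.028 with print-tip loess), and hypoxia targets 2 of 8 higher and 0 lower, with CA12 at 0.087 ± 0.0037 [0.035 to 0.11]. Camera's direction for glycolysis was up, as was the median of its mean ratios (0.0055), while its mean was -0.019. Unfolded protein response genes had 1 of 5 higher (DNAJC3, 0.11 ± 0.0010) and 2 lower. Epithelial adhesion genes had 2 of 7 higher, among them the catenin gene CTNND1 at 0.087 ± 0.081 [0.045 to 0.10], and 1 lower. Mesenchymal and invasion genes had 6 of 14 higher, with MMP2 at 0.13 ± 0.033, and 3 lower, with the chemokine receptor gene CXCR4 at -0.13 ± 0.068 [-0.15 to -0.084]. The housekeeping genes had 2 of 5 higher and 0 lower. None of these lists passed camera, and their smallest adjusted p was 0.821.

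CD80, DCT and BCAN, which are known from antigen-presenting cells, melanocytes and brain, were among the 12 genes highest in BM, and nearly every spot lay above background in both channels. Signal that does not come from SW480 transcripts may account for part of this, since 53 of 54 control oligonucleotide spots (98.1%, lower bound of the exact 95% interval 90.1%) were above background in all 4 samples. What these controls match is not given in the sources used here, so they decide nothing, and in the MRS samples they stood at a median of 5.58 and 6.80 times their local background, while 14.2% and 13.1% of other spots were dimmer than their median raw intensity. Broad expression of the printed genes in SW480 stays open too: 7 of 8 probes of leukocyte markers (87.5%) were above background, but 97.2% of all non-control spots were, which fixes the outcome for almost any 8 probes. The leukocyte markers PTPRC and LYZ stood at log2 intensities of 12.4 and 11.6, and of 12.3 and 12.1, on arrays 1 and 2. GAPDH stood lower, at 8.82 and 9.44, as did ACTB, at 8.83 and 9.93. The other leukocyte markers were not compared in this way. Whether SW480 expresses a gene cannot be read from its spot being above background, or from how bright it is, alone.

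Duplicate spots of a probe gave like ratios on an array while the 2 arrays did not. A smooth gradient over the slide called for correlated neighbours, with a bound of 0.5 set beforehand. The ratios of adjacent spots of different probes correlated at 0.133 and 0.172 (95% interval of the latter 0.14 to 0.20, taking pairs that share spots as independent). These values lie well below that bound but above 0, so they argue against a strong gradient and leave a weaker spatial part open. An effect of the printed position or source well may separate the arrays, and so may a different RNA response in the 2 pairs of cultures. For probes printed at 5 or more positions with all spots above background (GAPDH and 1 unnamed probe), the SD between positions was a median of 0.470 of the SD between different probes. The bounds set were at least 0.5 for the position and under 0.25 for the RNA response. Over all 5 such probes, with dim spots left out, it was 0.506 (0.179 to 0.859), just past the bound for the position, but that value was chosen after the first was seen. The 2 explanations cannot be told apart on so few probes, and the values of the first 2 ran from 0.179 (GAPDH, array 2) to 0.790.

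The 2 arrays correlated weakly but above 0 across genes. A residual intensity trend or saturation at the extremes is a candidate explanation, since r was 0.292 in the dimmest and 0.312 in the brightest 10% of genes and 0.0633 over the middle 80%, but the bootstrap 95% interval of the last (0.0023 to 0.12) held both bounds set for it. A gene-specific dye effect and a response to the postbiotic both predict a positive r over all genes, as the 0.108 was, but not its size. They cannot be told apart without a dye swap. ABCC4, ABCC3 and NQO1, which handle foreign compounds, would be genes to measure again with the dyes exchanged, as would SLC22A3. None of these genes passed over all genes after loess. Camera gave an adjusted p of 0.25 for the drug efflux list and 0.844 for the aryl hydrocarbon receptor list. For the drug efflux list it moved to 0.0713 with print-tip loess and to 0.408 with median centring.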
